A study of Mus musculus with 8 samples.

How the data were processed

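RNA was sequenced from EpCAM-positive cells that were sorted by flow cytometry from pancreatic tumours of KPC-luciferase mice. These mice (strain FVB/NJ) carry floxed p53 alleles, Pdx1-Cre and a luciferase reporter. The mice were 42 to 43 days old at the start and received gemcitabine and either control IgG or an antibody against LIF, with 4 tumours in each arm (n = 4 libraries each, 1 library per mouse). Per the submitters' processing notes, read quality was checked with FastQC 0.11.2, reads were aligned to mm10 with STAR 2.4.0k, and exonic reads were counted with HOMER, whose version is not given in the sources used here. The authors' notes name edgeR 3.6.8 for their own comparison, whose output was not used here. The strand setting, the annotation version and any filter on reads are not given in the sources used here.

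The deposited count table holds raw read counts, 1 transcript for each of 24537 genes, and every value in it is a whole number. The deposited FPKM table holds FPKM, reads scaled by transcript length and by library total. Each FPKM value was checked against the count divided by the transcript length and by the library total printed in the file header. All 168000 values of the 21000 transcripts present in both tables matched within 0.002 FPKM (100%). There were 0 unused columns of values for single samples. Genome coordinates are those of the count table, on mm10.

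Library totals per the file headers ran from 18954525 to 24681702 reads. Counts in genes were 16175021, 17374041, 18972281 and 17501361 for IgG libraries KPCL-PCC_203_G, KPCL-PCC_343_G, KPCL-PCC_345_G and KPCL-PCC_393_G. For anti-LIF libraries KPCL-PCC_227_GA, KPCL-PCC_310_GA, KPCL-PCC_354_GA and KPCL-PCC_391_GA they were 18562458, 15205928, 16561889 and 15135457. Counts in genes averaged 17505676 ± 1145850 for IgG and 16366433 ± 1604450 for anti-LIF (mean ± SD, n = 4 each; exact two-sided permutation p = 0.343). The reads carry no molecular identifiers, so a limit from a count of 0 covers counting error only. That limit was set at 3 counts over the 4 libraries of an arm.

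Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr at its default settings, which left 14711 genes, and libraries were scaled by TMM (trimmed mean of M values). The arms were compared with edgeR's quasi-likelihood test, and p values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are anti-LIF minus IgG with their standard error (SE), and positive values are higher with anti-LIF. CPM are counts scaled to the TMM library size, and log2 CPM values for scores used a prior count of 2. With 4 tumours against 4 there are 70 assignments of the labels, and the smallest exact two-sided permutation p is 0.0286.

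Gene lists for cell types, pathways and sample quality were written before the data were examined, as were the grouping, the main test and the alternatives to it. Of 45 lists, 43 had at least 5 tested genes. The erythroid list had 0 tested genes and the list of replication histones had 4, and neither was tested. Each list was compared with the other tested genes by limma's camera with a preset correlation of 0.01, and again with the correlation estimated from the data. The lists were also tested with limma's fry, which asks only whether the members of a list move. A score for each list and library was the mean log2 CPM of its tested members, and scores of the arms were compared by the exact permutation test. Reactome gene sets of 15 to 300 tested genes were tested by camera in the same way, with the mouse sets supplied in fgsea 1.28.0.

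Single genes were named by a rule fixed in advance. The rule takes the 10 largest fold changes in each direction among genes past the threshold whose arms do not overlap, genes fixed for the question (such as Lif, Lifr and Epcam), the 4 members with the lowest p of each list that passed, and 2 members of other lists of interest. It gave 109 genes. Some of these genes and 1 of the lists are not reported. Any other gene named was chosen after its value was seen.

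The alternatives were other scaling factors, DESeq2 1.42.0, limma-voom with and without sample weights, robust dispersion, limma-trend on log2 FPKM with a pseudocount of 1 or 0.1, other filters on low counts, 1 surrogate variable (sva 3.50.0), the acinar score as a covariate, and each library left out in turn. Added after the data were seen were the myeloid score as a covariate, scaling to the epithelial or to the myeloid list, leaving out a pair of libraries together, and each Reactome alternative. No pairing of mice was available, because no mouse number occurs in both arms. On simulated data with 4 against 4 libraries of this depth, edgeR recovered 8.96% of 67 genes changed 1.5-fold, 43.3% of 67 changed 2-fold and 89.4% of 66 changed 4-fold. Of 99 calls, 5 were false, and camera called the 1 list with a planted change and 0 of 40 lists without one. Genes were simulated independently, whereas the estimated correlation in the lists that passed ran from 0.12 to 0.75. The simulation thus does not show how often camera with the preset correlation calls lists falsely here. It changed 200 of 14711 genes, against 32.2% called in the data, so its recovery rates hold for that setting only.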

Results

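The comparison asks how transcripts in pancreatic tumour epithelium differ when the cytokine LIF (leukaemia inhibitory factor) is neutralised during chemotherapy. Every mouse received gemcitabine at 50 mg/kg on days 1 and 4 and antibody at 25 mg/kg on days 1, 3 and 5, either control IgG or anti-LIF. Tumours were collected on day 6, at about 48 days of age. The samples hold no arm without gemcitabine, so each value is a difference between antibodies on a background of gemcitabine.

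Relative to the tested genes as a whole, interferon-stimulated genes, pancreatic digestive-enzyme genes and macrophage markers were higher with anti-LIF, and epithelial keratins, laminins and duct genes were lower. Lif itself and its receptor gene Lifr were higher with the antibody, also relative to the tested genes as a whole. Targets of STAT3, the transcription factor that acts below the LIF receptor, did not move together as a group. Replication and mitosis genes were slightly higher, although the mitosis median turns to −0.11 with the acinar score as a covariate. These list results rest on a preset correlation between genes, and 0 of the 43 lists pass with an estimated one. Scaling the libraries to the epithelial or to the macrophage list moves all genes alike, by a median of 0.94 or −1.04, and leaves each of the 20 lists that passed on the same side of the other genes in camera, but 2 of them no longer pass with the former scaling and 9 with the latter. With the myeloid score as a covariate, 12 of the 20 lists no longer pass, among them the interferon and epithelial lists, and the YAP list passes in the opposite direction. The 12 include the myeloid list itself, whose loss is fixed by construction. The myeloid and acinar scores do not overlap between the arms (correlation with arm 0.93 and 0.87). Fits with either score as a covariate, here and below, therefore cannot separate that score from the antibody.

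**Figure D1:**
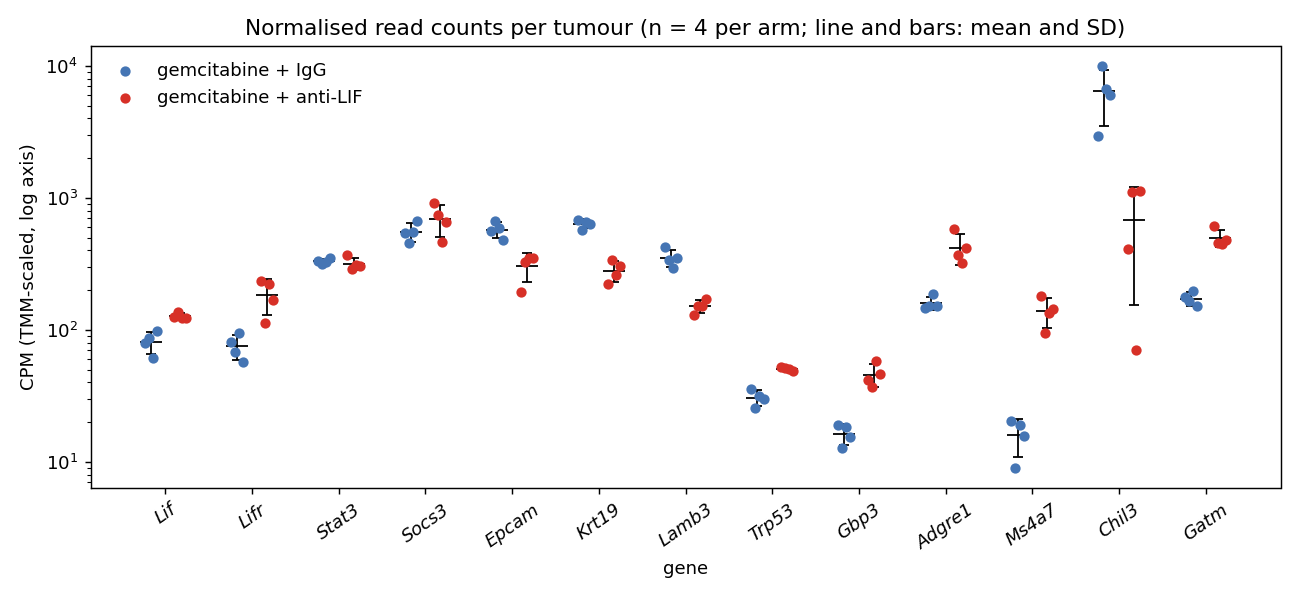
Expression of 13 genes in each tumour, as TMM-scaled CPM on a log axis, for control IgG and anti-LIF (points, tumours, n = 4 each; line and bars, mean and SD). Lamb3 averages 353 with IgG and 151 with anti-LIF, and Adgre1 averages 159 and 420.1.

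Lif (chromosome 11, 4266796 to 4272514) rose 1.56-fold, from 81.4 ± 15.6 to 127 ± 7.08 CPM (mean ± SD, n = 4; log2 fold change 0.64 ± 0.13 SE, adjusted p = 0.00965). Lifr (chromosome 15, 7140542 to 7197489) rose 2.46-fold, from 75.4 ± 16.2 to 185 ± 55.9 CPM (1.30 ± 0.24, adjusted p = 0.00663). In both genes all 4 anti-LIF libraries lay above all 4 IgG libraries. Il6st, which encodes the shared receptor chain gp130, differed by less than the spread between tumours, with 135 ± 8.95 and 133 ± 8.37 CPM. The same held for the gene Stat3, with 331 ± 15.1 and 317 ± 34.0 CPM (log2 fold change −0.06, adjusted p = 0.651), although scaled by library size alone Stat3 passed at −0.23. Socs3, a feedback inhibitor induced by STAT3, stood at 553 ± 89.1 and 692 ± 185 CPM (adjusted p = 0.255). Of 35 STAT3 target genes, 4 rose and 3 fell, against 4 and 2 when adjusted over the list alone (camera adjusted p = 0.348). Among them Tnfrsf12a fell 2.47-fold and Batf rose 1.81-fold. In the list of the LIF receptor chain, 5 of 19 genes rose and 3 fell, against 5 and 4 when adjusted over the list alone (camera adjusted p = 0.944). In the same libraries the myeloid list went from 3.05% to 5.88% of counts and the epithelial list from 0.910% to 0.425%. Scaling to the myeloid list moves all genes by a median of −1.04, more than the change in Lif. Whether the values in this paragraph reflect epithelial cells was not tested.

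The marker used for the sort, Epcam (chromosome 17, 87635979 to 87651127), fell from 575 ± 76.8 to 305 ± 74.8 CPM (−0.91 ± 0.20, adjusted p = 0.0102). Krt19 fell 2.27-fold and Krt8 2.13-fold, while the epithelial splicing regulators Esrp1 and Esrp2 fell 2.70-fold and 2.09-fold. Of 40 epithelial identity genes, 33 fell and 0 rose, against 38 and 0 when adjusted over the list alone, with a median of −0.87. Camera gave the list an adjusted p of 6.14e-15 with the preset correlation, and an adjusted p = 0.664 with an estimated correlation. With the myeloid score as a covariate the epithelial median was −0.0413 and the list no longer passed (adjusted p = 0.249). The list held 0.910% ± 0.0718 of counts with IgG and 0.425% ± 0.111 with anti-LIF (exact two-sided permutation p = 0.0286), while in the same libraries the myeloid list went from 3.05% ± 0.380 to 5.88% ± 1.64 (exact two-sided permutation p = 0.0286).

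Genes of the basement membrane and of the YAP programme were lower too. Scaled to the epithelial list, both lists still lay below the other genes in camera (adjusted p = 3.46e-06 and 2.80e-05). Their medians there were 0.19 and 0.13, against 0.94 for all genes and 0.015 for the epithelial list itself. The epithelial list too passed downward there (adjusted p = 2.32e-15), so camera on this scale does not test a fall beyond the epithelial genes. The basement membrane and YAP lists did not pass when libraries were scaled to the myeloid list (0.612 and 0.0738). Their medians of −1.70 and −1.79 there stand against −1.04 for all genes. Lamb3, a laminin chain (chromosome 1, 193302243 to 193343878), fell 2.34-fold, from 353 ± 53.5 to 151 ± 16.2 CPM (−1.22 ± 0.13, adjusted p = 0.00235). Lama5 fell 2.54-fold, and the integrin gene Itgb6 fell 1.91-fold. Across 32 basement membrane genes, 16 fell and 2 rose, and 18 and 2 when adjusted over the list alone (median −0.69, camera adjusted p = 7.58e-04, adjusted p = 0.664 with an estimated correlation). Among 22 YAP targets, 12 fell and 0 rose, and 13 and 0 when adjusted over the list alone (median −0.76, camera adjusted p = 7.58e-04, adjusted p = 0.664 with an estimated correlation). Ctgf fell from 1001 ± 269 to 298 ± 135 CPM, and F3 fell 2.91-fold. With the myeloid score as a covariate the YAP list turned and passed upward (median 0.45, adjusted p = 0.00307), and the basement membrane median turned to 0.38 (adjusted p = 0.170). With the acinar score as a covariate the YAP list did not pass (−0.36, adjusted p = 0.0808). In the same libraries the myeloid list rose from 3.05% to 5.88% of counts.

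Lineage programmes of the tumour epithelium followed the same direction. Scaled to the epithelial list, each list still lay below the other genes in camera (adjusted p from 9.10e-08 to 0.00830). Their medians there were 0.12 to 0.38, against 0.94 for all genes and 0.015 for the epithelial list. These medians thus show no fall beyond the epithelial genes. None of the lists passed when libraries were scaled to the myeloid list (0.642 to 0.990). Medians of −1.53 to −1.77 there stand against −1.04 for all genes. The myeloid share of counts went from 3.05% to 5.88% in the same libraries. With the myeloid score as a covariate none of these lists passed, and the ductal (0.15), progenitor (0.0586) and basal (0.74) medians turned positive; with the acinar score the gastric (−0.38) and basal (−0.73) lists did not pass. Of 28 gastric metaplasia genes, 9 fell and 0 rose, and 10 and 0 when adjusted over the list alone (median −0.72, camera adjusted p = 7.58e-04, adjusted p = 0.713 with an estimated correlation); Ctse fell 2.34-fold. Of 21 ductal genes, 9 fell and 2 rose, and 10 and 2 when adjusted over the list alone (median −0.67, camera adjusted p = 0.0206, adjusted p = 0.719 with an estimated correlation); without IgG library KPCL-PCC_203_G (−0.67) or by library size alone (−0.81) it no longer passed, and without IgG library KPCL-PCC_393_G and anti-LIF library KPCL-PCC_227_GA together the ductal median was −0.24 (adjusted p = 0.0520). Slc4a4 fell 3.04-fold and the abundant Clu fell from 11390 ± 1198 to 6330 ± 1066 CPM. Of 30 progenitor and stem genes, 15 fell and 3 rose, and 16 and 3 when adjusted over the list alone (median −0.55, camera adjusted p = 0.00204, adjusted p = 0.664 with an estimated correlation). Aldh1a1 fell 3.03-fold, Aldh1a3 2.02-fold and Prom1 1.99-fold. Of 32 classical subtype genes, 11 fell and 1 rose, and 12 and 1 when adjusted over the list alone (median −0.53, camera adjusted p = 0.00148, adjusted p = 0.713 with an estimated correlation). The gene that rose, Lyz2, is also in the myeloid list, whereas Krt20 fell 3.21-fold and Erbb3 2.35-fold. Of 13 basal and squamous genes, 3 fell and 0 rose, by either adjustment, over all genes or adjusted over the list alone (median −0.76, camera adjusted p = 0.0240, adjusted p = 0.664 with an estimated correlation); they were Anxa8, Dsg3 and Sprr1a, and the gene Sprr1a no longer passed with any of IgG library KPCL-PCC_343_G (−1.69), IgG library KPCL-PCC_393_G (−1.03) or anti-LIF libraries KPCL-PCC_227_GA (−1.41), KPCL-PCC_354_GA (−1.48) or KPCL-PCC_391_GA (−1.70) left out. The list basal_squamous itself no longer passed without anti-LIF library KPCL-PCC_227_GA (−0.57) or by library size alone (−0.90), nor without that library and IgG library KPCL-PCC_393_G together (−0.46, adjusted p = 0.0539).

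Macrophage genes were abundant in both arms and did not move alike. Ms4a7 (chromosome 19, 11321039 to 11334695) rose 8.64-fold, to 139 ± 34.8 CPM (3.11 ± 0.28, adjusted p = 0.00206). Ccr2, the chemokine receptor of recruited monocytes, rose 4.22-fold, Aif1 rose 3.50-fold and Adgre1, which encodes F4/80, rose 2.65-fold. Of 26 myeloid markers, 18 rose and 0 fell, and 19 and 0 when adjusted over the list alone, with a median of 0.89. Camera gave an adjusted p of 9.97e-09, and an adjusted p = 0.664 with an estimated correlation. Chil3, a chitinase-like protein secreted by macrophages (chromosome 3, 106147554 to 106167564), fell 9.43-fold, from 6398 ± 2891 to 678 ± 525 CPM (−3.24 ± 0.78, adjusted p = 0.0153). The C-type lectin genes Cd209f and Cd209g rose 43.2-fold and 47.4-fold, and Fcrls, an Fc receptor-like gene of tissue macrophages, rose 33.5-fold. Reads of Cd209 family members can be shared between close copies, so their division among copies is uncertain. Of 14 lymphoid genes, 5 rose and 0 fell, and 8 and 0 when adjusted over the list alone (median 1.12; camera adjusted p = 0.00135, adjusted p = 0.664 with an estimated correlation). Cd4 rose 3.00-fold, from 7.452 to 22.34 CPM, and Foxp3 1.51-fold, from 15.22 to 23.03 CPM. Cd3g, of the same list, averaged only 0.3639 CPM with IgG and 1.497 CPM with anti-LIF. The lymphoid list, with 14 of 26 listed genes tested, held 0.006028% of counts with IgG and 0.009854% with anti-LIF. Which cells gave the Cd4 and Foxp3 reads was not tested. With the myeloid score as a covariate the lymphoid median was 0.34 and the list no longer passed (adjusted p = 0.429).

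Interferon-stimulated genes rose in anti-LIF tumours. Of 48 on the list, 39 rose and 0 fell, and 41 and 0 when adjusted over the list alone, with a median of 1.26. Camera gave an adjusted p of 3.99e-16, and an adjusted p = 0.664 with an estimated correlation. With the myeloid score as a covariate the interferon median was 0.23 and the list no longer passed (adjusted p = 0.0870). Gbp3 (chromosome 3, 142560496 to 142573212) rose 2.80-fold, from 16.4 ± 2.91 to 45.8 ± 9.06 CPM (1.48 ± 0.17, adjusted p = 0.00284), Trim30a rose 2.78-fold and Bst2 2.37-fold. Of 21 genes for MHC class I and its peptide loading, 19 rose and 0 fell, by either adjustment, over all genes or adjusted over the list alone (median 0.84; camera adjusted p = 1.58e-10, adjusted p = 0.664 with an estimated correlation). With the myeloid score as a covariate the MHC class I median was 0.30, and the list still passed in camera (adjusted p = 0.0145). The immunoproteasome genes Psmb8, Psmb9 and Psmb10 rose 1.94-fold, 1.96-fold and 1.78-fold and the peptide trimmer Erap1 rose 1.82-fold. Psmb8 and Psmb9 belong to both lists, and reads of the H2 genes can be shared between close copies. The list of NF-kB and inflammation genes had 13 of 34 up and 2 down, and 14 and 2 when adjusted over the list alone (median 0.29; camera adjusted p = 0.0193, adjusted p = 0.664 with an estimated correlation). Without IgG library KPCL-PCC_345_G the NF-kB median was 0.21 and the list no longer passed, nor did it when libraries were scaled to the epithelial list (adjusted p = 0.0727). Ptgs2 rose 1.72-fold and Nfkb1 1.51-fold. The myeloid list went from 3.05% to 5.88% of counts in the same libraries.

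Digestive-enzyme genes of pancreatic acinar cells gave the largest increases. The gene Pnlip, pancreatic lipase (chromosome 19, 58670365 to 58681788), went from 1.52 ± 2.05 to 291 ± 195 CPM (7.60 ± 1.21, adjusted p = 0.00469); IgG library KPCL-PCC_203_G holds 4.42 CPM of it, and without that library the log2 fold change is 9.03. The gene Ctrc rose 38.0-fold (log2 5.25, or 4.59 without anti-LIF library KPCL-PCC_354_GA) and Gatm, an enzyme of creatine synthesis, rose 2.90-fold, from 172 ± 19.6 to 499 ± 76.5 CPM. The trypsin genes Gm5771, Prss1, Prss3 and Try4 had 5, 5, 58 and 178 counts over the IgG arm and 2301, 602, 3007 and 7328 over the anti-LIF arm, and their reads can be shared between close copies. All IgG counts of Prss1 lie in library KPCL-PCC_203_G, which holds the most of the other trypsin genes in that arm too, so the size of these rises depends on it. Of 38 acinar genes, 31 rose and 0 fell, and 34 and 0 when adjusted over the list alone, with a median of 3.33. Camera gave an adjusted p of 5.52e-13, and an adjusted p = 0.664 with an estimated correlation. The acinar list held 0.573% ± 0.156 of counts with IgG and 1.54% ± 0.787 with anti-LIF (exact two-sided permutation p = 0.0571). Its member Dmbt1, also made elsewhere, stood at 3873 ± 636 CPM with IgG and 3333 ± 941 with anti-LIF. The share therefore does not measure acinar RNA alone, least of all with IgG. Acute-phase genes, a list that holds the Reg3 and Saa families, had 13 of 23 up and 1 down, by either adjustment, over all genes or adjusted over the list alone (median 1.17; camera adjusted p = 7.58e-04, adjusted p = 0.664 with an estimated correlation). Itih4 rose 9.41-fold, and Reg3a rose from 6.94 ± 6.50 to 174 ± 95.3 CPM (the gene Reg3a changed by 4.66 on the log2 scale, or 5.42 without IgG library KPCL-PCC_203_G), with reads that can be shared between Reg3 copies. With the acinar score as a covariate the acute-phase median was 0.16 and the list no longer passed (adjusted p = 0.0593). Acinar and acute-phase genes rose in libraries whose myeloid share also rose, from 3.05% to 5.88% of counts.

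Proliferation genes were higher by small amounts relative to the tested genes as a whole. Of 43 S-phase genes, 12 rose and 0 fell, and 11 and 0 when adjusted over the list alone (median 0.39; camera adjusted p = 1.98e-04, adjusted p = 0.719 with an estimated correlation). Pola1 rose 2.13-fold, from 15.4 ± 3.09 to 32.6 ± 3.98 CPM, and Mcm5 rose 2.12-fold. Of 54 G2 and M genes, 14 rose, none of which passed when adjusted over the list alone, where 0 rose (median 0.33, or −0.11 with the acinar score as a covariate; camera adjusted p = 1.35e-04, adjusted p = 0.719 with an estimated correlation). Mki67 rose 1.66-fold and Top2a 1.97-fold. Of 35 DNA repair and fork genes, 7 rose and 1 fell, and 6 and 1 when adjusted over the list alone (median 0.29; camera adjusted p = 0.0193, adjusted p = 0.730 with an estimated correlation); without anti-LIF KPCL-PCC_310_GA the median was 0.18 and the list no longer passed, nor did it when libraries were scaled to the myeloid list (adjusted p = 0.0988). Parp1 rose 1.75-fold. The unfolded-protein list had 14 of 33 up and 2 down, and 15 and 2 when adjusted over the list alone (median 0.19; camera adjusted p = 0.00163, adjusted p = 0.664 with an estimated correlation), with Sdf2l1 up 2.06-fold; scaled to the myeloid list it did not pass (adjusted p = 0.826). Of 29 immediate-early genes, which also respond to tissue dissociation, 5 rose and 0 fell, and 3 and 0 when adjusted over the list alone (median 0.38; camera adjusted p = 0.0185, adjusted p = 0.664 with an estimated correlation). Scaled to the epithelial list the immediate-early genes did not pass (adjusted p = 0.116), and with the myeloid score as a covariate their median turned to −0.28. With the acinar score as a covariate the S-phase (0.12), DNA repair and unfolded-protein (0.0360) lists did not pass, nor did the unfolded-protein list with the myeloid score (0.28). The S-phase (0.69), G2 and M (0.67) and DNA repair (0.38) medians were larger with the myeloid score. Those lists passed in camera there (adjusted p = 1.75e-09, 1.90e-05 and 3.82e-05). The myeloid share of counts went from 3.05% to 5.88% in the same libraries.

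Genes that handle gemcitabine did not move as a group, with 3 of 30 up and 6 down, and the same numbers when adjusted over the list alone (camera adjusted p = 0.838). Dck, which encodes the kinase that activates gemcitabine, rose 1.51-fold, from 34.8 ± 2.02 to 52.6 ± 5.34 CPM (0.60 ± 0.09, adjusted p = 0.00444), and the nucleoside transporter gene Slc29a1 rose 1.44-fold. Of 29 p53 response genes, 6 rose and 4 fell, and the same numbers when adjusted over the list alone (camera adjusted p = 0.944). Trp53 (chromosome 11, 69580359 to 69591873) rose 1.65-fold, from 30.7 ± 4.31 to 50.6 ± 1.36 CPM (0.72 ± 0.11, adjusted p = 0.00406). It is floxed in these mice, and its reads from recombined and from other cells were not told apart. Pdx1 did not pass (6.78 ± 1.70 and 4.47 ± 1.62 CPM, adjusted p = 0.145). Among the mesenchymal genes Zeb2 rose (log2 fold change 1.00 ± 0.21) and Loxl2 fell 2.19-fold, and the list as a whole did not pass (1 of 27 up and 6 down, the same when adjusted over the list alone; camera adjusted p = 0.144). With the myeloid score as a covariate 0 of the 14711 tested genes passed. That score does not overlap between the arms, so its fit decides nothing about the genes in this paragraph. In the same libraries the myeloid share of counts went from 3.05% to 5.88%. Whether these changes arose in epithelial cells was not tested.

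Of the 10 genes named for the largest falls, all but Chil3 averaged under 10 CPM with IgG. Obp2a, an odorant-binding protein, had 59 counts over the IgG arm and 0 over the anti-LIF arm, so it was at least 16.4-fold lower against a floor of 3 counts over the 4 libraries. The non-coding 9030619P08Rik had 110 counts with IgG and 2 with anti-LIF. Mchr1, a receptor for melanin-concentrating hormone, fell 18.6-fold, from 6.52 ± 0.734 to 0.347 ± 0.246 CPM (−4.22 ± 0.40, adjusted p = 0.00206). Lims2, a focal-adhesion protein, fell 9.82-fold and Mrap, an accessory protein of melanocortin receptors, fell 11.5-fold. Cpa4, a carboxypeptidase, fell 12.9-fold and Btn1a1, a butyrophilin, 11.6-fold.

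**Figure D2:**
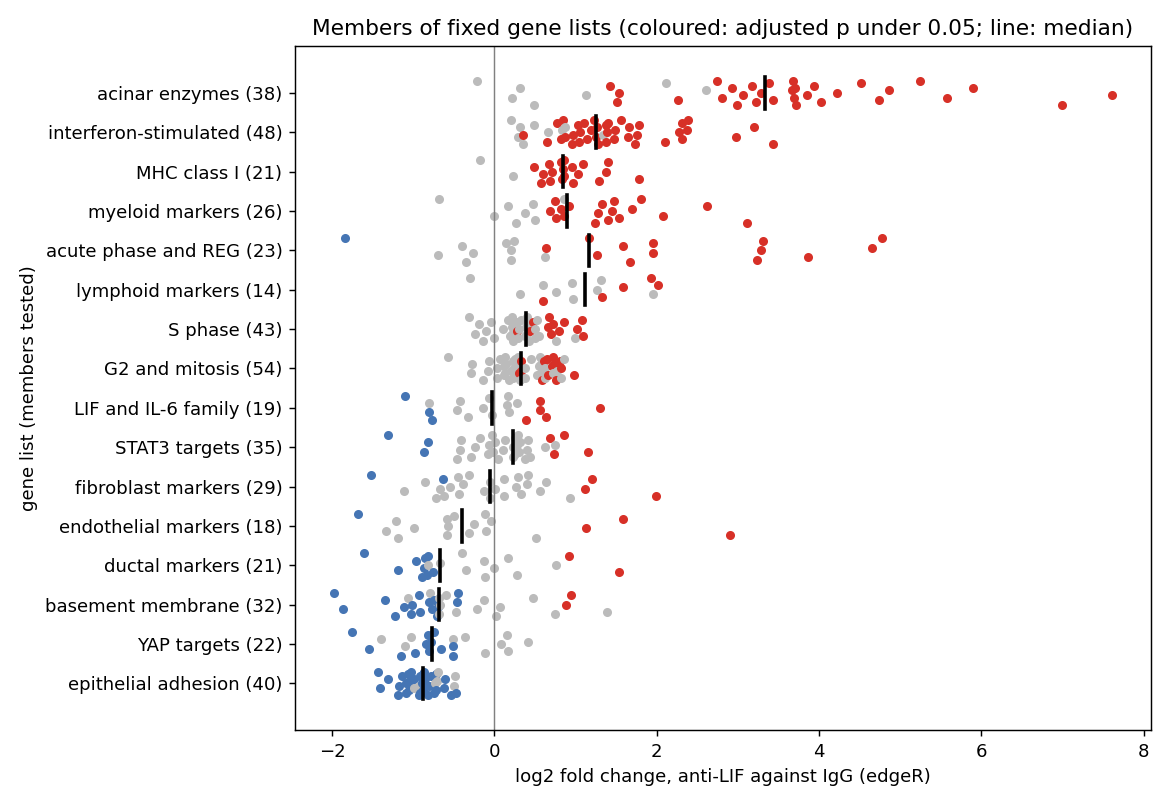
Log2 fold change (anti-LIF minus IgG, TMM scale) of each tested member of 16 gene lists, with 1 point per gene, coloured where the adjusted p is under 0.05, and a black line at the median (n = 4 tumours per arm). The median runs from 3.33 for acinar genes to −0.87 for epithelial identity genes.

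Of the 14711 genes tested by edgeR's quasi-likelihood test, 2303 were higher and 2428 lower with anti-LIF at an adjusted p under 0.05, together 32.2% of the tested genes. At least a 2-fold change was fitted for 698 of the higher and 901 of the lower genes. Without IgG library KPCL-PCC_343_G there were 1467 higher and 1507 lower, and without anti-LIF library KPCL-PCC_354_GA there were 1521 lower. The higher share of the calls was 48.7% with TMM, 28.6% by library size alone, 32.5% and 32.8% on log2 FPKM with a pseudocount of 1 or 0.1, 98.0% when scaled to the epithelial list and 1.84% when scaled to the myeloid list. Those scalings moved the median of all genes by −0.16, −0.10, −0.12, 0.94 and −1.04, so each change is given relative to the tested genes as a whole. The libraries of the arms did not overlap for 5259 genes (35.7%), where chance gives 2.86%. With the myeloid or the acinar score as a covariate 0 genes passed in edgeR (955 and 993 at an unadjusted p under 0.05), and those scores themselves do not overlap between the arms.

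The first principal component held 60.5% of the variance of the 500 most variable genes and separated the arms. Of 43 gene lists, 12 passed upward and 8 downward in camera with the preset correlation, and 0 passed with an estimated correlation, where the adjusted p ran from 0.664 to 0.988. By limma's fry, 12 lists passed in 1 direction. Scores of 17 lists reached the smallest exact two-sided permutation p of 0.0286, and 0 of them passed after Benjamini-Hochberg adjustment (0.0723 at the lowest). Without IgG libraries KPCL-PCC_203_G, KPCL-PCC_343_G, KPCL-PCC_345_G and KPCL-PCC_393_G in turn, 11, 7, 9 and 7 scores reached it. Genes with at least 1 count numbered 18045.8 ± 92.3 per IgG library and 17548.2 ± 226 per anti-LIF library (exact two-sided permutation p = 0.0286). IgG library KPCL-PCC_393_G was the only library with more than 7 counts of Xist (15126), and it had 3, 2, 0 and 1 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty; the sex of the mice is not given in the sources used here.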

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

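Chosen only after their results were seen were the splits for the higher and the lower genes, the check of myeloid members against their list's mean, the comparisons of the myeloid score with the fibroblast, endothelial, neutrophil and interferon scores, the shares of counts set beside them, the wording that sets what those score comparisons can decide, and the reading of the check of acinar members.

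A sample was singled out when, within an arm of 4 tumours, its gap to the nearest other value took an unusually large part of the arm's whole range. This happened in 20 of 324 groups of 4 values, where chance alone expects 16.2, so the number is close to what chance gives. IgG library KPCL-PCC_393_G and anti-LIF library KPCL-PCC_227_GA hold 5 each. In IgG library KPCL-PCC_393_G, Xist stood at 817.5 CPM against 0.172 to 0.354 in the other IgG libraries, Kdm5d at 0 against 32.6 to 36.0 and Uty at 0.0541 against 29.9 to 34.6. The same library had 182.3 CPM of Aldh1a3 (122.5 to 128.6 in the others) and 156.5 of Anxa8 (103.9 to 112.2). In anti-LIF library KPCL-PCC_227_GA, Epcam stood at 194.2 CPM against 326.2 to 352.7, Dsg3 at 0.192 against 1.07 to 1.17 and Uty at 46.5 against 29.0 to 31.4. That library also had the fewest genes with a count, 17212 against 17624 to 17682, and the lowest TMM factor, 0.844 against 0.978 to 0.986.

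The other values that stood apart lay in single genes or scores. In IgG library KPCL-PCC_203_G, Prss1 was at 0.287 CPM against 0 in the other IgG libraries and Bmi1 at 33.7 against 40.4 to 41.5. In IgG library KPCL-PCC_343_G, Esrp1 was at 130.1 against 103.9 to 107.4. In IgG library KPCL-PCC_345_G, Adgre1 was at 185.6 against 146 to 152.3, the DNA repair score at 3.73 against 3.55 to 3.58 and the gastric metaplasia score at 5.92 against 5.44 to 5.47, as mean log2 CPM. In anti-LIF library KPCL-PCC_310_GA, Cpa4 was at 0.2003 CPM against 0.124 to 0.134 and Rmi2 at 3.54 against 2.02 to 2.04. In anti-LIF library KPCL-PCC_354_GA, Psmb8 was at 113.3 against 92.2 to 95.4, and in anti-LIF library KPCL-PCC_391_GA, Pdia6 was at 292 against 393.6 to 410.6.

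Of the 35 splits of the 8 libraries into 4 and 4, 1 split, the real one, gave as many as 2303 genes in 1 direction. The same split alone gave as many as 2428, and the highest other split gave 1 gene. A share of 1 of 35 is the lowest this test can give, and both counts come from the same split. The other splits mix the arms, which widens the spread within their groups. The result therefore argues against chance for both counts without excluding it. For gene lists called by camera with the preset correlation, 13 of the 35 splits gave 20 or more (highest other 27), so chance is not excluded. For Reactome sets, 15 of the 35 gave 41 or more and the highest other gave 165, so chance is not excluded. That split sets IgG libraries KPCL-PCC_203_G and KPCL-PCC_343_G with anti-LIF libraries KPCL-PCC_227_GA and KPCL-PCC_391_GA, and it called 0 genes in either direction.

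Myeloid markers, with interferon genes beside them, were higher with anti-LIF in cells sorted for EpCAM, a gate that should remove macrophages. A larger share of a single unchanged macrophage population, as the only source of these markers, would raise them alike. Of the 26, 57.69% departed from the list's mean (15 members, from Ms4a7 at 2.17 to Ly6c2 at −1.69 on the log2 scale). The abundant Ctss stood at 3218 CPM with IgG and 3202 with anti-LIF, while Apoe and Lyz2 rose to 21960 and 13510. These values argue against that population as the only source. Members also made by other cells would part from the mean too, so a larger macrophage share beside other sources stays open. The allowance made below for such members was applied to the acinar list only. A loss of epithelial cells that raises every other cell type alike stays open: the myeloid score rose by 1.067 over the fibroblast, 1.25 over the endothelial and 0.71 over the neutrophil score (exact two-sided permutation p of 0.0571, 0.0286 and 0.229, or 0.0857, 0.0857 and 0.229 adjusted over the 3), but the rise over fibroblast was 0.69 without anti-LIF library KPCL-PCC_227_GA and 0.43 without it and IgG library KPCL-PCC_393_G, where the fibroblast list passed upward (median 0.57, adjusted p = 0.0160), and the rise over neutrophil was 0.39 without the former and 0.47 without IgG library KPCL-PCC_203_G. Shares of counts went both ways, from 0.0163% to 0.0448% for endothelial, 0.0839% to 0.0336% for mesothelial and 0.256% to 0.151% for fibroblast genes (exact two-sided permutation p of 0.0286, 0.0286 and 0.0857), but each rests mostly on 1 gene (Lyve1 with 332 CPM with anti-LIF, Msln with 562 and Fbln2 with 1432 CPM with IgG), so they decide nothing. Whether interferon genes rose beyond the myeloid markers also stays open (0.28 more, exact two-sided permutation p = 0.2), and a change in macrophage state with the antibody may underlie the unequal markers, which was not tested separately.

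Epithelial genes fell together. Dilution of an unchanged epithelial population predicts equal falls, and 7.5% of the 40 members (3 genes) departed from the list's mean, which is consistent with dilution by other RNA. The 3 were Esrp1 (−0.54), Lsr (0.39) and Tjp3 (0.40). A response of the epithelium to the antibody in which these genes fall equally was not tested apart from dilution and stays open.

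Acinar genes rose by unequal amounts. A single library is argued against, since the lowest median with 1 library left out was 2.925 (without anti-LIF library KPCL-PCC_354_GA). Different amounts of a single unchanged acinar source stay open: 55.26% of the 38 members (21 genes) departed from the list's mean, from Pnlip at 4.99 to Dmbt1 at −3.59, but members also made elsewhere, such as Dmbt1 and Gatm (3873 and 172 CPM with IgG), lower that mean and would put acinar-only members above it under this explanation too. The bound set beforehand, by which so many departures exclude such a source, was wrong for that reason. Those members do not account for differences among the enzymes themselves, such as Pnlip (4.99) and Try4 (2.73) against Cpa1 (−0.15) and Ctrb1 (−0.21). Pnlip and Try4 stood at only 1.52 and 2.47 CPM with IgG, near the floor, so these differences were not read as deciding. RNA from acinar cells next to the tumour, and acinar gene expression in the sorted cells, may each contribute; no test separated these.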

How the results depend on the processing

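Chosen only after the data were seen were the myeloid covariate, the scalings to the epithelial and to the myeloid list, leaving out IgG library KPCL-PCC_393_G and anti-LIF library KPCL-PCC_227_GA together, and each Reactome alternative; the causes of the changes below were not tested unless stated.

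The 2303 higher genes became 1430 by library size alone, 1472 and 1458 on log2 FPKM with a pseudocount of 1 and 0.1, 10727 when scaled to the epithelial list and 228 when scaled to the myeloid list. The 2428 lower genes became 221 and 12145 under the latter pair of scalings, which by construction move all genes (medians 0.94 and −1.04). With the acinar or the myeloid score as a covariate, 0 genes were higher and 0 lower in edgeR (993 and 955 at an unadjusted p under 0.05); the scores do not overlap between the arms, so the covariate takes up the difference between arms. With 1 library left out, 1467 to 2218 genes were higher and 1507 to 2136 lower, the lowest without IgG library KPCL-PCC_343_G, and without anti-LIF library KPCL-PCC_354_GA there were 1521 lower. These fits have fewer libraries. Without IgG KPCL-PCC_393_G and anti-LIF KPCL-PCC_227_GA together there were 1656 higher and 1700 lower. Under scaling by RLE or upper quartile, DESeq2, voom, robust dispersion, other count filters and a surrogate variable, the higher count stayed within 1.5 times of 2303, and the lower within 1.5 times of 2428.

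The 20 gene lists called became 12 with the acinar covariate, where 11 of the 20 still passed and 9 did not. They became 0 with an estimated correlation, 12 by fry and 38 by fry for either direction. With the myeloid covariate 14 lists passed, although 12 of the 20 no longer did; the interferon median was 0.23 (adjusted p = 0.0870) in place of 1.26 and the epithelial median −0.0413 (0.249) in place of −0.87, both no longer past the threshold. Medians reversed there for the YAP (0.45, called upward at an adjusted p = 0.00307), mesenchymal (0.66), progenitor (0.0586), ductal (0.15) and basement membrane (0.38) lists. They also reversed for the basal (0.74), endothelial (0.61) and immediate-early (−0.28) lists. Of these, the mesenchymal and endothelial lists had not been called. The myeloid list's own score was the covariate, so its median near 0 (−0.0629) and its lost call were fixed by construction. For the classical list the median stayed negative (−0.10) while camera turned upward. Other lists that had not been called changed sign, among them fibroblast (1.56, adjusted p = 5.4e-08), WNT (0.27) and NOTCH (0.20). With the acinar covariate the G2 and M list reversed (−0.11), as did Ctrc (−0.012). Ctrc belongs to the acinar list, whose score is the covariate, so its value near 0 says little. Scaled to the myeloid list, the endocrine (−0.73), endothelial (−1.39) and oxidative phosphorylation (−0.95) lists, not called with TMM, changed direction in camera. They passed there (camera adjusted p = 0.00123 upward, 0.00492 upward and 0.0292 downward). Against −1.04 for all genes, the endothelial median lay below and the oxidative phosphorylation median above, opposite to camera. Camera's direction under this scaling therefore need not give the side on which a list's median lies. The 17 list scores at the smallest exact p became 7 to 20 with 1 library left out, with 11, 7, 9 and 7 without IgG libraries KPCL-PCC_203_G, KPCL-PCC_343_G, KPCL-PCC_345_G and KPCL-PCC_393_G.

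The 41 Reactome sets became 68 with the myeloid covariate, 195 and 24 when scaled to the epithelial and the myeloid list, 75 without IgG KPCL-PCC_393_G and anti-LIF KPCL-PCC_227_GA, 0 with an estimated correlation, and 36 to 78 with 1 library left out, the highest without anti-LIF library KPCL-PCC_227_GA. Of the 109 named genes, 95 kept direction and side of the threshold in each setting run on them, apart from the covariate and surrogate-variable fits. With those fits included, 3 did. The fit with the acinar covariate called 0 genes, so none of the 104 named genes past the threshold could keep its side there. The drop from 95 to 3 therefore does not measure how well those genes hold. The settings added after the data were seen were not run on the named genes. Among those settings, the scalings to the epithelial and to the myeloid list kept the sign of 3392 and 3080 of the 4731 genes called. On simulated data with 4 against 4 libraries of this depth and 200 changed genes, 8.96% of 1.5-fold changes were recovered, so small changes can be missed. That rate may differ in the data, where 32.2% of genes were called. No paired analysis was possible because no mouse number occurs in both arms.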

Other observations

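Chosen only after results were seen were the genes named in this part outside the fixed rule, while the Reactome test was fixed in advance. Among 609 Reactome sets, 33 passed upward and 8 downward in camera with the preset correlation, and 0 with an estimated correlation. Without anti-LIF library KPCL-PCC_227_GA, 78 sets passed in place of 41. Upward were interferon gamma signalling (45 of 79 genes up, median 0.76), class I antigen loading (22 of 33, 0.82), phagocytosis through Fc gamma receptors (28 of 69, 0.28), chemokine receptor binding (12 of 38, 0.58) and the complement cascade (9 of 16, 1.18). Downward were cell junction organisation (29 of 56 genes down, −0.56), laminin interactions (15 of 29, −0.68) and assembly of collagen fibrils (12 of 36, −0.51). These medians are on the TMM scale; scaling to the epithelial or the myeloid list moves the median of all genes by 0.94 and −1.04, and the direction of each set under those scalings is relative to that shift.

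Among the most abundant transcripts, Fn1 stood at 19310 ± 1769 and 18770 ± 3389 CPM and did not pass (adjusted p = 0.902). Apoe rose from 9040 ± 1730 to 21960 ± 10210 CPM (1.28 ± 0.34, adjusted p = 0.0209) and Lyz2 from 4177 ± 718 to 13510 ± 5782 CPM (1.69 ± 0.30, adjusted p = 0.00592). The lysosomal proteases differed from each other, since Ctsb rose from 2110 ± 301 to 4574 ± 1354 CPM (adjusted p = 0.00825) while Ctss stood at 3218 ± 531 and 3202 ± 256 CPM (adjusted p = 0.976). Lyve1 and Eng, of the endothelial list, rose by 2.90 and 1.59 on the log2 scale while Cldn5 fell (−1.68). Among the WNT targets Apcdd1 (−2.49) and Lgr5 (−1.16) fell and Ascl2 (1.57) rose.

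The remaining lists did not pass in camera with the preset correlation. In each case the numbers of genes up and down are over all tested genes, followed by those adjusted over the list alone. The closest were tuft (4 and 0 of 11; 5 and 0; adjusted p = 0.0571) and WNT targets (1 and 6 of 16; 2 and 8; 0.0571). MHC class II had 1 and 0 of 11 (1 and 0 alone, adjusted p = 0.0655) and TGF-beta targets 2 and 7 of 20 (2 and 7 alone, 0.0944). In camera MHC class II passed upward with the myeloid score as a covariate (median 1.90, adjusted p = 0.0015). It also passed upward without IgG library KPCL-PCC_393_G and anti-LIF library KPCL-PCC_227_GA together (0.70, 0.00337). Scaled to the myeloid list it passed on the upper side of the other genes (2.26e-05), and scaled to the epithelial list it did not pass (0.192). Cholesterol synthesis had 1 and 8 of 25 (1 and 8 alone, adjusted p = 0.136), oxidative phosphorylation 5 and 1 of 49 (0 and 0 alone, 0.165) and apoptosis 11 and 4 of 33 (13 and 4 alone, 0.348). The NRF2 list had 4 and 4 of 26 (4 and 6 alone, adjusted p = 0.366), NOTCH targets 2 and 4 of 12 (2 and 5 alone, 0.370) and fatty acid synthesis 5 and 5 of 27 (5 and 5 alone, 0.463). Neutrophil markers had 2 and 0 of 12 (2 and 0 alone, adjusted p = 0.4995), endothelial markers 3 and 1 of 18 (3 and 1 alone, 0.672) and hypoxia and glycolysis genes 2 and 2 of 36 (2 and 2 alone, 0.684). Ribosomal protein genes had 5 and 3 of 63 (4 and 1 alone, adjusted p = 0.813), fibroblast markers 3 and 2 of 29 (2 and 1 alone, 0.944), mesothelial markers 0 and 1 of 8 (0 and 1 alone, 0.944) and endocrine markers 0 and 1 of 23 (0 and 0 alone, 0.962). In 4 of the lists that did not pass, the median and camera's direction differ in sign.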
